A study of Arabidopsis thaliana with 11 samples.

How the data were processed

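The series measured polyA-selected RNA by paired-end sequencing in flower buds and leaves of wild-type Arabidopsis thaliana. Per the labels, the plants grew in soil in a greenhouse without treatment, tissue was taken at growth stage 6.0, RNA was extracted with a Qiagen RNeasy kit, libraries followed the TruSeq RNA protocol, and the fragment sizing was 260. The associated array series was not used here. There were 11 libraries from 6 biological samples, 2 of flower buds and 4 of leaves. Flower bud 1 and 2 and leaf 1 and 2 each had a HiSeq2000 library and a HiSeq2000 multiplex library, called the HiSeq run and the multiplex run of that sample. Leaf 1 had a second multiplex library, 1b, labelled as a technical replicate of 1a. Leaf 3 and 4 each had 1 library from a GA II, an older Illumina sequencer. The labels do not say whether numbered samples came from separate plants. P-values between tissues and between sequencers therefore measure the spread between these samples, which may be technical. Those for the difference between HiSeq and multiplex runs, and for its dependence on tissue, measure the spread left between runs of one sample.

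Per the submitters' processing notes, reads were handled with Bowtie2 2.0. Per the file headers, the authors deposited, for each of 28094 loci, a count of proper read pairs, a count of single reads, a count of pairs within an insert size limit, and the length of the sequence reads were counted on. Proper pairs had both mates on the same reference sequence. The insert limit was 500 in 10 libraries and 1000 in the HiSeq run of leaf 1a. The pair counts were raw, with a different total in each library, and each library had its own file. The genome build, the annotation release, the treatment of reads that fit several loci and the use of strand are not given in the sources used here. Loci with near-identical copies, such as the LHCB1 genes, PDF1.2 with PDF1.2c, and AOC1 with AOC2, are therefore uncertain, as are overlapping and antisense loci. No coordinates are given, because the build is not named. The reference TAIR10.1 served for gene names and GC content only, and 27320 of the 28094 locus identifiers matched it.

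Libraries held 34405145 to 192817049 counted pairs. A count of 0 pairs allows up to 3 pairs, which is 0.0156 CPM in the deepest library and 0.0872 CPM in the shallowest. Counting intervals are exact 95% intervals, and intervals and floors cover counting error only, since duplicate pairs are not independent molecules. CPM in the text are counts relative to library sizes scaled by TMM factors, means are over biological samples, and errors are SDs or, for log2 fold changes, standard errors. Loci with 0 pairs in one tissue are given as a lower bound against a floor of 3 pairs over the group. Loci with 1 to 3 pairs, and some with a few more, are given as a ratio of CPM with its counting interval. These bounds and ratios between tissues use the HiSeq runs alone, and those between leaf samples use the summed runs.

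Runs of one biological sample were summed. The pair counts were tested with edgeR 4.0.16 in R 4.3.3: TMM factors, the filterByExpr filter with its minimum count of 10, the quasi-likelihood F-test and Benjamini-Hochberg adjustment, with a locus called at an adjusted p under 0.05. The tissue comparison and the comparison of leaf samples between sequencers came from 1 fit of the 6 biological samples with tissue and sequencer as terms. In that fit the tissue difference comes from the 4 samples of the HiSeq2000, 2 of each tissue, while all 6 samples give the spread. The GA II leaf samples varied less, with a coefficient of variation of 10.7% against 31.2% to 39.8% between HiSeq2000 samples of one tissue. Adjusted p-values between tissues can therefore be too low for the spread of the HiSeq2000 samples. The run comparison and the test of whether the tissue difference depended on run type used 8 libraries, 1 HiSeq run and 1 multiplex run of each of 4 samples, with the sample as a block. The sets of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry. The adjusted p of fry is given for change in either direction unless a single direction is stated. Agreement between pairs of libraries was measured by the chi-square over loci with an expected count of 10 or more, divided by its degrees of freedom, and by the biological coefficient of variation from edgeR.

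The tests, their samples and covariates, 24 gene lists with 541 entries and the rule for named genes were set before the data were examined. The lists were floral organ identity; anther, tapetum and pollen wall; pollen and pollen tube; meiosis; cell cycle; shoot meristem; photosystems; Calvin cycle and photorespiration; chlorophyll synthesis; glucosinolates; salicylate and pattern-triggered defence; jasmonate; flavonoids; senescence; clock; flowering time; auxin and gibberellin; secondary cell wall; ribosomal proteins; guard cell and trichome; seed; root; heat, touch and wounding; and reference genes for qPCR. One entry, RPL11A, was left out because the reference gave its locus the symbol of another ribosomal protein, which left 540. Of the 541 entries, 491 matched a reference name, 16 matched in another spelling and 34 had no matching name. Apart from RPL11A, entries were kept by locus identifier whether or not the name matched. The rule named the 10 loci with the highest and the 10 with the lowest fold change between tissues among called loci with a mean of 50 CPM or more in the higher tissue and no overlap between the tissues' libraries. It also took up to 4 called members with the largest change from each list, with any called member against the list's median. For the other comparisons it took up to 5 called loci in each direction with a mean of 10 CPM or more.

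The fits were tested on simulated counts with 200 changed loci. In the tissue comparison, over 23685 loci, 6.0% of loci changed 2-fold, 62% changed 4-fold and 92% changed 8-fold were called, with 2 unchanged loci called. Between sequencers, over 23711 loci, the shares were 10% at 2-fold, 50% at 4-fold and 92% at 8-fold. Between run types, over 23233 loci, 92% at 2-fold were called, and for the dependence on run type, over 23241 loci, also 92%. Between tissues 12339 loci were called in the data, far more than the 200 changed here, so these shares need not hold there. A locus also had the same dispersion in all simulated samples, while the GA II leaf samples varied less in the data. In a simulation over 24043 loci that raised the cell cycle list alone, camera called that list (adjusted p = 8.41e-30) and 0 others, and its adjusted p was 0.0220 with an estimated correlation. Loci were drawn independently, while the estimated correlation of that list in the data was 0.721. The simulation therefore does not measure false calls of lists at the preset correlation in the data.

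Alternatives were other scalings, other filters on low counts, DESeq2 1.42.0, libraries thinned to the smallest total, organelle loci left out, other choices of runs and samples, each sample left out in turn, a sequencer term left out, a replicate block, glmTreat, limma-voom with the sample as a random effect, and loess trends on GC content and length removed with a span of 0.3. GC content was known for 98.6% of the loci tested between sequencers. Summaries and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.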

Results

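The series compared the transcriptomes of flower buds and leaves of wild-type Arabidopsis thaliana at the growth stage at which the first flower opens. Flower buds gave 2 biological samples and leaves gave 4, 11 libraries in all. Both flower bud samples and leaf 1 and 2 were sequenced on a HiSeq2000, each in a HiSeq run and in a multiplex run, and leaf 3 and 4 on a GA II. The 4 HiSeq runs held 182707504 to 192817049 counted read pairs each, and the other 7 libraries held 34405145 to 41105722. Summed over runs, the flower bud samples held 218477506 and 217267500 pairs, leaf 1 and 2 held 271060494 and 225332585, and leaf 3 and 4 held 35302492 and 37682650. The most abundant locus of both flower bud samples was RBCS1A, a small subunit of Rubisco, at 0.513% of the pairs of the HiSeq run of flower bud 1 and 0.642% in that of flower bud 2. In the HiSeq runs of leaf 1 and 2 it was RCA, the Rubisco activase, at 1.73% and 1.46%.

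Flower buds were compared with leaves to find the genes that differ between the tissues. Of the genes of floral organ identity, of the anther and of pollen, 18 of 22, 29 of 30 and 27 of 27 were higher in flower buds, with medians of 8.23, 11.32 and 7.18 on the log2 scale. Of the genes of meiosis, the cell cycle and cytosolic ribosomes, 19 of 24, 32 of 32 and 22 of 24 were higher, with medians of 2.52, 4.99 and 1.64. Of the ribosomal genes, 0 were called with no sequencer term, a setting that compares flower buds with all 4 leaf samples. Of the genes of photosystems, glucosinolates and salicylate defence, 44 of 50, 25 of 30 and 21 of 24 were lower, with medians of -2.01, -2.98 and -2.36. The lists called by camera numbered 15, of which 0 were called with an estimated correlation, where the lowest adjusted p was 0.0590. By fry in a single direction all lists were called but chlorophyll synthesis, jasmonate, flowering time and reference genes. The adjusted p of these was 0.0830, 0.0675, 0.182 and 0.0502. Root markers, at 0.361 by camera, had 0.000910 by fry, so the tests of lists disagreed. Of 24043 loci tested, 7322 were called higher and 5017 lower in flower buds by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 6907 and 4263 changed by more than 2-fold. Adjusted p-values of genes are from that test, and those of gene lists are from camera unless fry is named.

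Of 22 regulators of floral organ identity, 18 were higher in flower buds and 0 lower, or 20 and 1 adjusted over the list alone. Their median log2 fold change was 8.23, or 8.04 with regulators at 0 pairs in leaves set to their bound (adjusted p = 9.72e-11; adjusted p = 0.180 with an estimated correlation). STK, a MADS-box gene of ovule identity, stood at 25.2 ± 14.7 CPM in flower buds (SD, n = 2), with 12824 pairs in their HiSeq runs and 0 in those of leaves, at least 3002-fold higher. CRC, a regulator of carpel development, was at least 1817-fold higher, at 15.7 ± 7.80 CPM. LFY, which specifies the floral meristem, was at least 296-fold higher, and SUP, which bounds the stamen whorl, at least 271-fold. The 4 that did not pass, named after their values were seen, were SEP4, FUL, SPT and AP2, with adjusted p of 0.0580, 0.573, 0.0618 and 0.0809. SEP4 had a log2 fold change of -0.58.

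Genes of the tapetum, the anther layer that feeds pollen, and of the pollen coat gave the highest median of the 24 lists. Of 30 anther, tapetum and pollen wall genes, 29 were higher and 1 lower, also when adjusted over the list alone, with a median of 11.32 on the log2 scale, or 11.20 at the bound (adjusted p = 1.27e-19; adjusted p = 0.0590 with an estimated correlation). GRP17, an oleosin of the pollen coat, reached 1589 ± 930 CPM in flower buds (SD, n = 2). Its 788644 pairs in the flower bud HiSeq runs stood against 2 in leaves, a ratio of 276948 with a counting interval from 76667 to 2286850. EXL6, a lipase of the pollen coat, had 120811 pairs against 0, at least 28284-fold, and LTP12, a tapetal lipid transfer protein, had 124441 against 3, a ratio of 29133 (interval 9969 to 141272). In the leaf multiplex runs EXL6 had 14 pairs and GRP17 had 118, which is why these ratios use the HiSeq runs alone. The single lower gene was TPD1, a secreted ligand that sets tapetum fate, at 4.51 ± 0.692 CPM in flower buds and 14.4 ± 4.88 in leaf 1 and 2 (SD, n = 2 each; edgeR adjusted p = 0.00555).

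All 27 genes of pollen and the pollen tube were higher in flower buds, also when adjusted over the list alone, with a median of 7.18 (adjusted p = 2.49e-14; adjusted p = 0.0590 with an estimated correlation). PPME1, a pectin methylesterase of pollen, rose by 10.49 ± 0.58 on the log2 scale (SE) to 309 ± 29.1 CPM (SD, n = 2). The ratio of PRF5, a pollen profilin, was 3530 (interval 1378 to 12956). HTR10, a histone H3 of the male germline, had 2641 pairs against 1, a ratio of 1855 (interval 333 to 73291). Of 24 meiosis genes, 19 were higher and 0 lower, also when adjusted over the list alone, with a median of 2.52 (adjusted p = 9.89e-05; adjusted p = 0.258 with an estimated correlation). DMC1, the meiotic recombinase, rose by 3.60 ± 0.36 (SE), from 1.60 ± 0.131 CPM in leaf 1 and 2 to 19.5 ± 6.06 in flower buds (SD, n = 2 each). SYN1, the meiotic cohesin, rose by 3.95 ± 0.54 and RCK, a helicase of crossover formation, by 4.15 ± 0.71 (edgeR adjusted p = 0.00328 or less for these 3 genes). Without flower bud 1, 12 of the meiosis genes were called higher, and 11 with no sequencer term.

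All 32 cell cycle and DNA replication genes were higher in flower buds, also when adjusted over the list alone, with a median of 4.99 (adjusted p = 7.25e-12; adjusted p = 0.407 with an estimated correlation). TPX2, a spindle protein, stood at 31.3 ± 0.430 CPM in flower buds, 0.411 ± 0.343 in leaf 1 and 2, and 4.01 ± 0.215 in leaf 3 and 4 (SD, n = 2 each). CYCB1;1, a mitotic cyclin, rose by 6.21 ± 0.55 on the log2 scale and HIK, a kinesin of cytokinesis, by 6.03 ± 0.80 (SE; edgeR adjusted p = 0.00117 or less). The number called was 19 with no sequencer term. Among 21 genes of the shoot meristem and organ boundaries, 14 were higher and 1 lower, or 15 and 1 adjusted over the list alone, with a median of 4.07 (adjusted p = 3.06e-05; adjusted p = 0.210 with an estimated correlation). WUS, which maintains stem cells of the meristem, had 7409 pairs against 0, and STM, a KNOX gene of meristem identity, had a ratio of 1892 (interval 869 to 5157). CLV1, the receptor kinase that limits the stem cell domain, was the lower gene and fell by 2.58 ± 0.33 on the log2 scale (SE; edgeR adjusted p = 0.00107).

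Of 24 cytosolic ribosomal protein genes, 22 were higher and 0 lower, also when adjusted over the list alone, with a median of 1.64 (adjusted p = 9.08e-05; adjusted p = 0.412 with an estimated correlation). RPS6A rose by 2.51 ± 0.40 on the log2 scale (SE) to 395 ± 199 CPM in flower buds, while leaf 3 and 4 stood at 307 ± 21.6 (SD, n = 2 each). With no sequencer term 0 of these genes were called, and the adjusted p of RPS6A was 0.324. Of 13 secondary cell wall genes, 10 were higher and 0 lower, or 11 and 0 adjusted over the list alone, with a median of 2.48 (adjusted p = 0.00491; adjusted p = 0.499 with an estimated correlation). NST1, a NAC factor of wall thickening, rose by 5.97 ± 0.67, MYB46, which acts downstream of it, by 3.66 ± 0.56, and the laccase LAC17 by 3.13 ± 0.54 (log2, SE; edgeR adjusted p = 0.00335 or less).

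Of 50 genes of photosystems, light harvesting and electron transport, 44 were lower in flower buds and 0 higher, or 50 and 0 adjusted over the list alone, with a median of -2.01 (adjusted p = 1.24e-11; adjusted p = 0.430 with an estimated correlation). PSAD2, a subunit of photosystem I, stood at 169 ± 145 CPM in flower buds, 1010 ± 241 in leaf 1 and 2 and 2680 ± 653 in leaf 3 and 4 (SD, n = 2 each; edgeR adjusted p = 0.0177). Without flower bud 1, 18 of the list were called lower, without flower bud 2 29, and without leaf 3, without leaf 4 or with the HiSeq2000 samples alone 27. Of 32 genes of the Calvin cycle and photorespiration, 28 were lower and 0 higher, or 29 and 0 adjusted over the list alone, with a median of -2.23 (adjusted p = 2.08e-12; adjusted p = 0.401 with an estimated correlation). RCA fell from 17586 ± 3720 CPM in leaf 1 and 2 to 1740 ± 1022 in flower buds (SD, n = 2 each; edgeR adjusted p = 0.00563). GOX1, the glycolate oxidase of photorespiration, fell by 3.25 ± 0.49 on the log2 scale and GLDP1, a subunit of glycine decarboxylase, fell by 3.20 ± 0.52 (SE). Of 14 chlorophyll synthesis genes, 7 were lower and 0 higher, also when adjusted over the list alone, with a median of -1.23 (adjusted p = 0.0102; adjusted p = 0.499 with an estimated correlation). CRD1, a cyclase subunit of that pathway, fell by 1.87 ± 0.43. Without flower bud 1 or without leaf 1, 4 chlorophyll genes were called lower, and without leaf 1, 1 was called higher.

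Glucosinolates are sulphur-rich defence compounds of the cabbage order. Of 30 genes of their synthesis and breakdown, 25 were lower and 0 higher, or 27 and 0 adjusted over the list alone, with a median of -2.98 (adjusted p = 2.19e-11; adjusted p = 0.344 with an estimated correlation). CYP79F1, which starts synthesis from methionine derivatives, stood at 2.59 ± 0.230 CPM in flower buds and 400.2 ± 231 in leaf 1 and 2 (SD, n = 2 each). BCAT4, which starts chain elongation of methionine, fell by 6.97 ± 0.50 on the log2 scale and MYB51, a regulator of indole glucosinolates, fell by 6.30 ± 0.44 (SE; edgeR adjusted p = 0.000179 or less for these 3 genes). MYB76, a regulator of the aliphatic branch, had 0 pairs in the flower bud HiSeq runs and 531 in those of leaves, at least 252-fold lower. Without leaf 1, 3 of the list were called higher.

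Of 24 genes of salicylate and pattern-triggered defence, 21 were lower and 0 higher, or 21 and 1 adjusted over the list alone, with a median of -2.36 (adjusted p = 7.85e-10; adjusted p = 0.0590 with an estimated correlation). CBP60g, a regulator of salicylate synthesis, fell by 6.55 ± 0.53 and PR5, a pathogenesis-related protein, fell by 4.85 ± 0.47 on the log2 scale (SE; edgeR adjusted p = 0.000381 or less). PR2, a glucanase induced by salicylate, fell by 7.17 ± 0.68 against leaf 1 and 2. It stood at 1.74 ± 1.24 CPM in flower buds and 2.89 ± 0.0380 in leaf 3 and 4 (SD, n = 2 each), and with no sequencer term its adjusted p was 0.0968. In that setting 13 of the list were called lower, and without leaf 1, 1 was called higher.

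Jasmonate genes moved in both directions. Of 28, 9 were higher and 6 lower, or 10 and 6 adjusted over the list alone, with a median of 0.04 (adjusted p = 0.996, and fry's adjusted p = 8.22e-05 for change in either direction). Over all 24043 tested loci 7322 were higher and 5017 lower, which are similar shares. For change in either direction fry's adjusted p was 0.0287 or less for every list, so it does not set jasmonate genes apart. Higher members were the stamen regulators MYB21 (ratio 1814, interval 986 to 3783), MYB24 and MYB57, and the vegetative storage protein VSP1, at 3172 ± 133 CPM in flower buds and 3.43 ± 3.41 in leaf 1 and 2 (SD, n = 2 each; edgeR adjusted p = 0.000753). Lower members included the synthesis genes AOS, which fell by 4.09 ± 0.32, AOC1, which fell by 3.26 ± 0.38, and OPCL1, which fell by 2.73 ± 0.45 (log2, SE; edgeR adjusted p = 0.00266 or less). AOC2, a close copy of AOC1, and the signalling genes MYC2 and COI1 were the other lower members. The adjusted p of MYC2 was 0.0673 without flower bud 1, and that of COI1 was 0.168 with no sequencer term.

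Flavonoid and anthocyanin genes were also divided. Of 24, 11 were higher and 8 lower, also when adjusted over the list alone, with a median of 1.25 (adjusted p = 0.583). Without flower bud 1, 5 were called higher, without flower bud 2, 4 were called lower, and with no sequencer term 1 was called lower, PAP1. TT12, a flavonoid transporter, had 468 pairs in the flower bud HiSeq runs and 0 in those of leaf 1 and 2, at least 109.6-fold higher. Leaf 3 and 4 stood at 0.330 ± 0.134 CPM against 0.943 ± 0.248 in flower buds (SD, n = 2 each), and with no sequencer term its adjusted p was 0.295. PAP1, a MYB activator of anthocyanin synthesis, fell by 4.21 ± 0.39, and UGT75C1, an anthocyanin glucosyltransferase, fell by 3.15 ± 0.50 (log2, SE; edgeR adjusted p = 0.00246 or less). The adjusted p of UGT75C1 was 0.0681 with no sequencer term.

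Of 20 senescence and chlorophyll breakdown genes, 4 were higher and 11 lower, also when adjusted over the list alone, with a median of -1.36 (adjusted p = 0.00798; adjusted p = 0.258 with an estimated correlation). SWEET15, a sucrose transporter, rose by 4.85 ± 0.55 and DIN2, a beta-glucosidase gene induced in the dark, by 3.96 ± 0.70, while JUB1, a NAC factor that delays senescence, fell by 4.31 ± 0.57 (log2, SE; edgeR adjusted p = 0.00355 or less). With no sequencer term 2 of the list were called higher and 1 lower, and the adjusted p of JUB1 was 0.199. Of 22 clock and photoperiod genes, 2 were higher and 8 lower, or 2 and 7 adjusted over the list alone, with a median of -1.24 (adjusted p = 0.0333; adjusted p = 0.258 with an estimated correlation). BOA, an evening gene, rose by 6.51 ± 0.49, and CDF1, a repressor of CO, fell by 3.64 ± 0.40 (log2, SE). With no sequencer term 1 of the list was called lower and the adjusted p of CDF1 was 0.0512. LUX, a member of the evening complex, was the other higher gene at 2.43 ± 0.53, but with no sequencer term its log2 fold change was -0.85 with an adjusted p of 0.672. Without leaf 2, 4 of the list were called higher.

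Of 15 flowering time genes, 6 were higher and 6 lower, also when adjusted over the list alone. Their median was -0.14 and their mean 0.14 (adjusted p = 0.459), and the median was 0.10 with upper quartile factors and 0.43 with library size only. Only 2 were called lower with no sequencer term. SVP, a repressor of flowering, fell by 4.21 ± 0.26 on the log2 scale (SE; edgeR adjusted p = 0.000114), from 188 ± 3.62 CPM in leaf 1 and 2, with 145 ± 4.35 in leaf 3 and 4 (SD, n = 2 each). SPL15, an age-pathway factor, rose by 5.36 ± 0.44, and SPL9, of the same family, by 2.40 ± 0.22 (log2, SE). FLC, a repressor of flowering, rose by 4.89 ± 1.14 against leaf 1 and 2, but leaf 3 and 4 stood at 4.65 ± 0.271 CPM against 3.10 ± 0.799 in flower buds, and with no sequencer term its adjusted p was 0.884.

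Of 26 auxin and gibberellin genes, 12 were higher and 5 lower, also when adjusted over the list alone, with a median of 0.63 (adjusted p = 0.232). The gibberellin synthesis genes GA3ox3, at least 211-fold higher, and GA20ox2, with a ratio of 258 (interval 136 to 565), led the higher genes, with the auxin response factor MP at 4.51 ± 0.45 (log2, SE). The auxin transporter PIN4 fell by 2.78 ± 0.32. The number called lower was 2 with no sequencer term, and 3 without flower bud 1, with the HiSeq2000 samples alone or with library size only.

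The lists of other cell types and of handling were small. Of 7 root markers, 3 were higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.361): the iron transporter IRT1 had 4065 pairs in the flower bud HiSeq runs and 0 in those of leaves, at least 952-fold higher, and the nitrate transporter NRT2.1 fell by 7.54 ± 1.07 (log2, SE; adjusted p = 0.0723 by limma-voom). The number of root markers called lower was 1 without flower bud 1, flower bud 2 or leaf 1, since CASP1, a protein of the root endodermis, had an adjusted p of 0.112, 0.0983 and 0.0690. PLT2, a regulator of root stem cells and one of the higher genes, had 0.158 and 0.122 without flower bud 1 and 2, and 0.267 by DESeq2. Of 9 guard cell and trichome markers, 1 was higher and 5 lower, also when adjusted over the list alone, with a median of -0.96 (adjusted p = 0.135), and 2 were called lower with library size only or with no sequencer term, and 3 without flower bud 2 or without leaf 2. None was called higher without flower bud 1. MYB60, a guard cell factor, fell by 2.58 ± 0.27. More of the guard cell and trichome markers were called higher than lower with library size only. Of 4 seed markers tested, SESA4, a seed storage albumin, was higher, with 434 pairs against 0, and 0 were lower, also when adjusted over the list alone (adjusted p = 0.564). Without leaf 1, 2 seed markers were called higher and 1 lower. Of 12 heat, touch and wounding genes, 1 was higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.127): the calmodulin-like TCH3 fell by 3.72 ± 0.29 and the zinc finger gene ZAT10 fell by 4.65 ± 0.48. The higher gene was HSP18.2, a small heat shock protein, at 3.87 ± 0.354 CPM in flower buds, 0.819 ± 0.294 in leaf 1 and 2 and 2.75 ± 0.00554 in leaf 3 and 4 (SD, n = 2 each). Its adjusted p was 0.253 with no sequencer term. Without leaf 1 the number called lower was 6. Of 13 reference genes for qPCR, 0 were higher and 2 lower, also when adjusted over the list alone (adjusted p = 0.218): UBQ10 fell by 1.84 ± 0.41 and ACT2 fell by 1.45 ± 0.32. More of the reference genes were called higher than lower with library size only. With no sequencer term 0 of the reference genes were called and without leaf 2 4 were called lower, and the list's median of -0.23 became 0.36 with library size only.

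**Figure D1:**
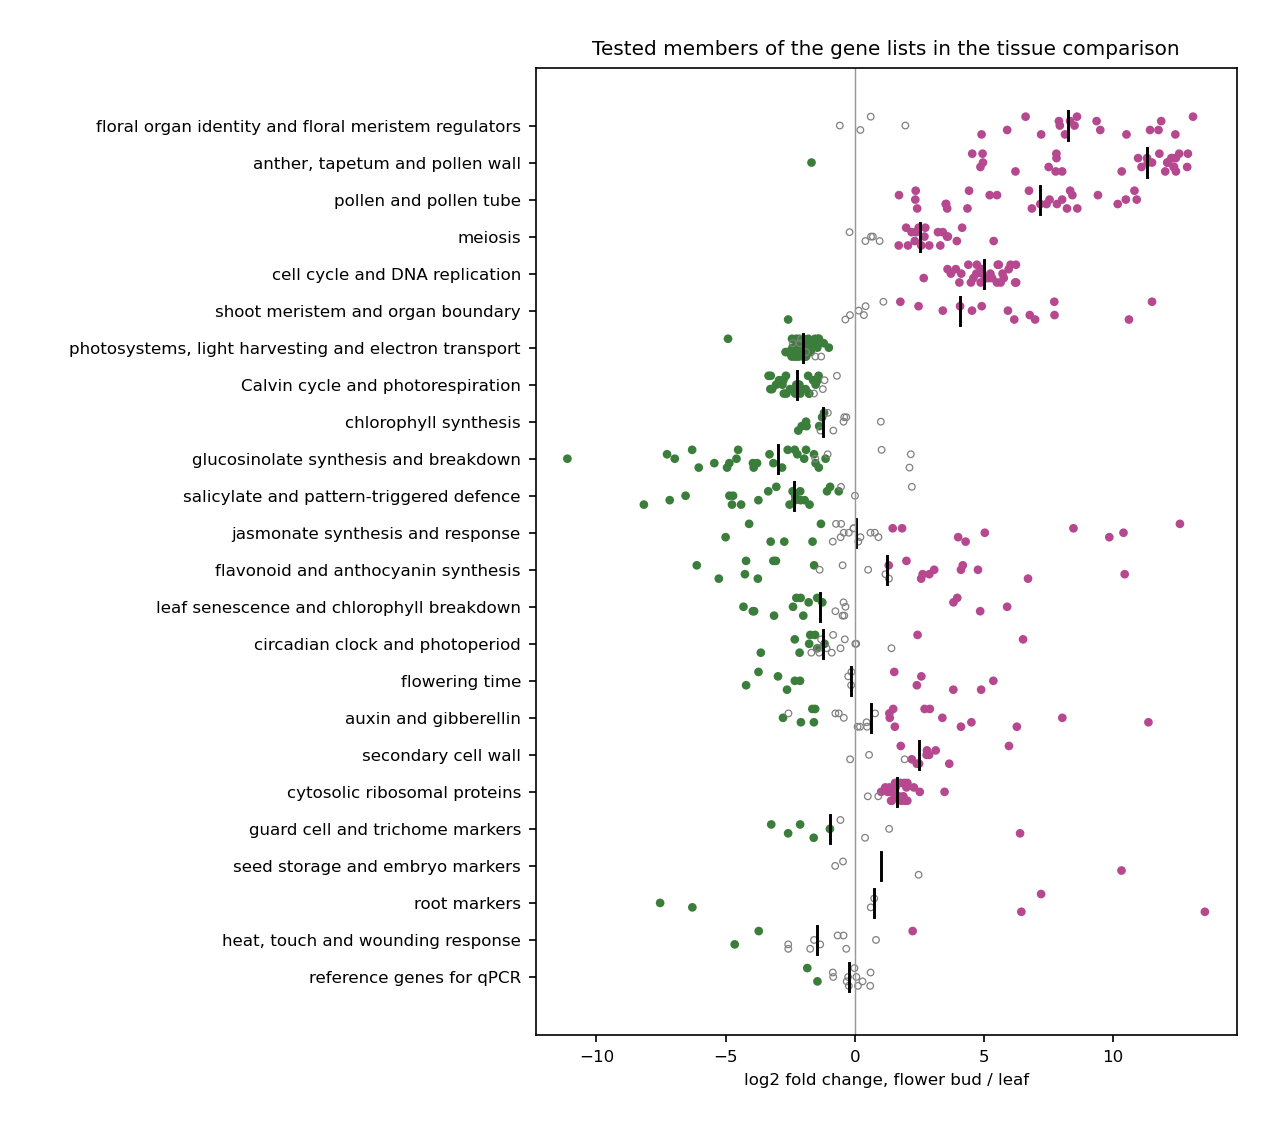
Log2 fold change of flower buds over leaves (x axis) for each tested member of the 24 gene lists (y axis), from the fit of 2 flower bud and 4 leaf samples with a sequencer term. Filled points were called by edgeR's quasi-likelihood test, open points were not, and the black bar is the list's median, from 11.32 for the anther list to -2.98 for glucosinolates, with those of flowering time and of reference genes changing sign with library size only.

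Outside the lists, the most restricted abundant loci of flower buds included XTH3, a cell wall transglucosylase, with 165112 pairs in the HiSeq runs against 0 in leaves, at least 38655-fold higher. A Kunitz-type protease inhibitor, AT1G72290, was at least 14771-fold higher, the cytochrome P450 CYP705A24 at least 9845-fold, a GH3-family gene, AT5G13380, at least 9416-fold, a lipid-transfer-type gene, AT4G14815, at least 8729-fold, and a pectin lyase-like gene, AT3G07830, at least 6062-fold. A9, a tapetal gene that is also in the anther list, had 27507 pairs against 1, and the lipase gene AT1G20130 had 231504 against 9, a ratio of 18066 (interval 9517 to 39510). On the leaf side, PDF1.2, a defensin induced by jasmonate and ethylene, fell by 12.06 ± 1.31 on the log2 scale (SE; edgeR adjusted p = 0.000566), with 393 ± 438 CPM in leaf 1 and 2 (SD, n = 2), 703 in leaf 1 and 83.9 in leaf 2, and 0.0913 ± 0.0266 in flower buds. That flower bud value sums HiSeq runs, at 0.0704 and 0.0257 CPM of PDF1.2, and multiplex runs, at 0.347 and 0.334. PCR1, a cadmium resistance protein, fell by 10.62 ± 0.48, IGMT4, a methyltransferase of indole glucosinolates, fell by 10.26 ± 0.69, the receptor-like kinase CRK4 fell by 9.64 ± 0.90, GolS2, a galactinol synthase, fell by 9.47 ± 1.05, and MSRB6, a methionine sulfoxide reductase, fell by 9.15 ± 1.48. Leaf 3 and 4 stood at 1.41 and 2.15 CPM for PDF1.2, and GolS2 stood at 1.41 and 2.08 there, 320 ± 219 in leaf 1 and 2 and 0.452 ± 0.415 in flower buds (SD, n = 2 each). The adjusted p with no sequencer term was 0.0519 for PDF1.2 and 0.0771 for GolS2. The other lower loci were the thionin AT1G66100, the methyltransferase AT1G15125, the TRAF-like AT2G32870 and AT3G16670, an Ole e 1 family gene with 1.14 CPM in leaf 2 and 97.3 or more in the other leaf samples. The adjusted p of AT3G16670 was 0.00579, and 0.0706 without flower bud 1 and 0.0544 without flower bud 2. By limma-voom over the 11 libraries the adjusted p was 0.0921 for XTH3, 0.151 for GRP17, 0.168 for MSRB6 and 0.489 for AT3G16670.

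**Figure D2:**
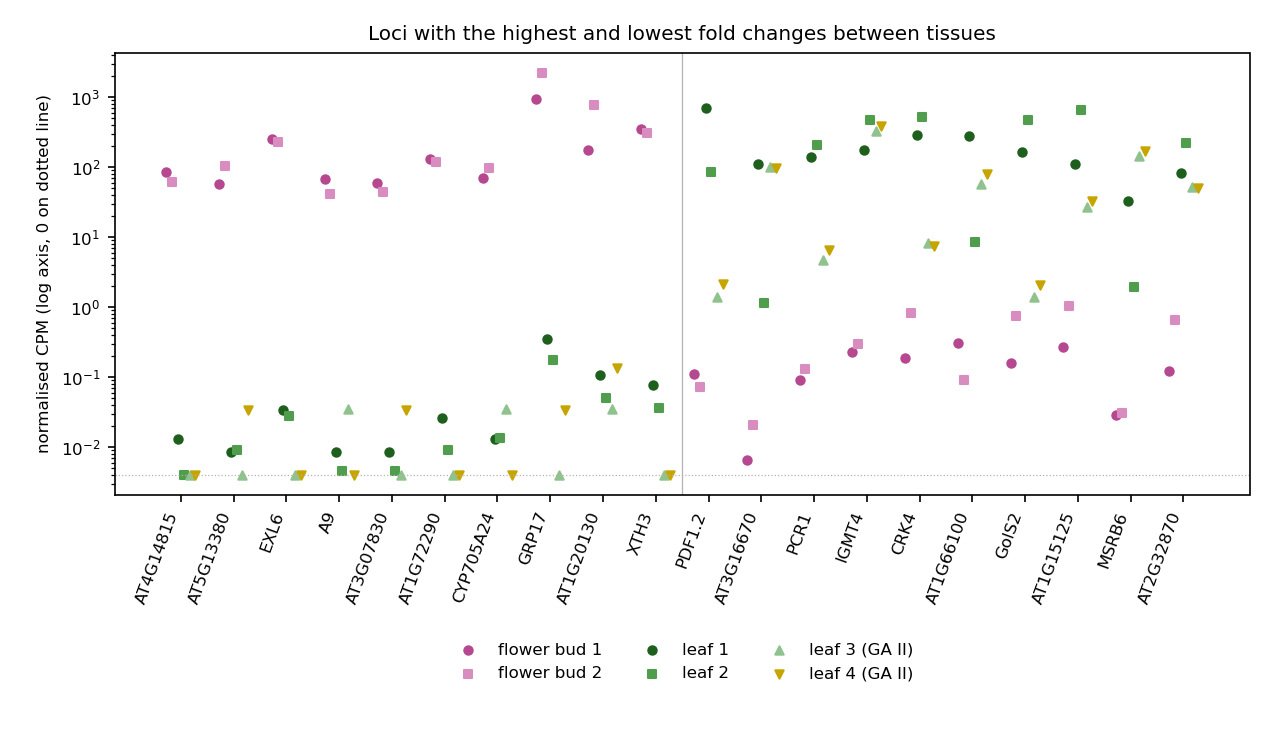
Normalised CPM (y axis, log scale, with 0 drawn on the dotted line) of the 10 loci with the highest and the 10 with the lowest fold change between tissues (x axis) in each of the 6 biological samples. Flower bud samples lie above all 4 leaf samples for the 10 loci on the left, such as GRP17 at 1589 ± 930 CPM (SD, n = 2), and below them for the 10 on the right, a separation that the rule for naming them asked for.

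Within the HiSeq2000 samples alone, 6379 loci were higher and 3888 lower, and with no sequencer term 4796 and 2397. Without flower bud 1 the counts were 4596 higher and 3754 lower. The share called higher, 59.3%, rested on the scaling: with library size only it was 77.7%, with 10405 loci higher and 2991 lower and the median of all loci shifted by 0.58 on the log2 scale, and with upper quartile factors it was 67.3%, with a shift of 0.24.

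No locus was called different between the HiSeq and the multiplex runs of the same samples. RBCS1A took 0.513% of the pairs of flower bud 1 in the HiSeq run and 0.514% in the multiplex run, and RCA took 1.73% of those of leaf 1a in both. Of 23663 loci tested, 0 were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 3404 at an unadjusted p under 0.05, and 0 were called by DESeq2, with 193 at that level. With RLE, upper quartile and library-size scaling 15, 9 and 4 loci were called. Within the leaf samples alone 23 loci were called, and within the flower bud samples alone 6. The chi-square per degree of freedom between the HiSeq and the multiplex run was 1.00 to 1.03 in the 4 samples, at or just above counting noise. Counting the runs of a sample as 1, with 1b included, had been set before the data were examined. Leaf 1a and 1b gave 4.49, and their coefficient of variation was 4.36%. Different samples of one tissue and run type gave 160 to 1115 on the HiSeq2000, with coefficients of variation of 31.2% to 39.8%, and the GA II leaf samples gave 18.7 and 10.7%. This chi-square grows with depth: between flower bud 1 and 2 it was 765 in the HiSeq runs and 160 in the multiplex runs. In the multiplex runs, nearer in depth to the GA II libraries, it was 160 to 250.

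The test of whether the tissue difference depended on run type named 8 loci, given here with their pairs in the tissue where each was scarce. GRP17 had 2 and 0 pairs in the HiSeq runs of leaf 1a and leaf 2 but 30 and 39 in their multiplex runs. The HiSeq runs of leaf 1a and leaf 2 held 192817049 and 187815247 pairs in all, and the multiplex runs 41105722 and 37517338. MEE48, a glucanase-like gene that is the A6 member of the anther list, had 0 and 0 pairs in the leaf HiSeq runs and 7 and 11 in the multiplex runs, XTH3 had 0 and 0 against 10 and 8, EXL6 had 0 and 0 against 6 and 6, and GRP16, another pollen coat oleosin, had 0 and 0 against 4 and 6. In flower buds, PDF1.2 had 17 and 6 pairs in the HiSeq runs against 17 and 15 in the multiplex runs, PDF1.3, a related defensin, had 0 and 0 against 3 and 4, and PCR1 had 18 and 25 against 10 and 13, with an adjusted p of 0.0469. The call of PCR1 was lost in 9 settings, with an adjusted p of 0.0985 with RLE factors, 0.0946 with library size only, 0.367 without flower bud 1 and 0.210 without flower bud 2. That of PDF1.3 was lost without flower bud 2, with 0.0580. In thinned libraries 7 of these 8 loci lost their call, all but MEE48. Of 23663 loci, 157 were called by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the multiplex runs the size of the tissue difference was smaller at 75 of these and larger at 82. The log2 fold change of flower buds over leaves was higher there at 4 and lower at 153, by over 2-fold at 4 and 39. The count was 37 with RLE factors, 40 with library size only and 29 with DESeq2, and without leaf 1 it was 711, of which 658 went the other way. Without leaf 2 it was 161, with 144 the other way, without flower bud 1 it was 81 and without flower bud 2 it was 349.

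**Figure D3:**
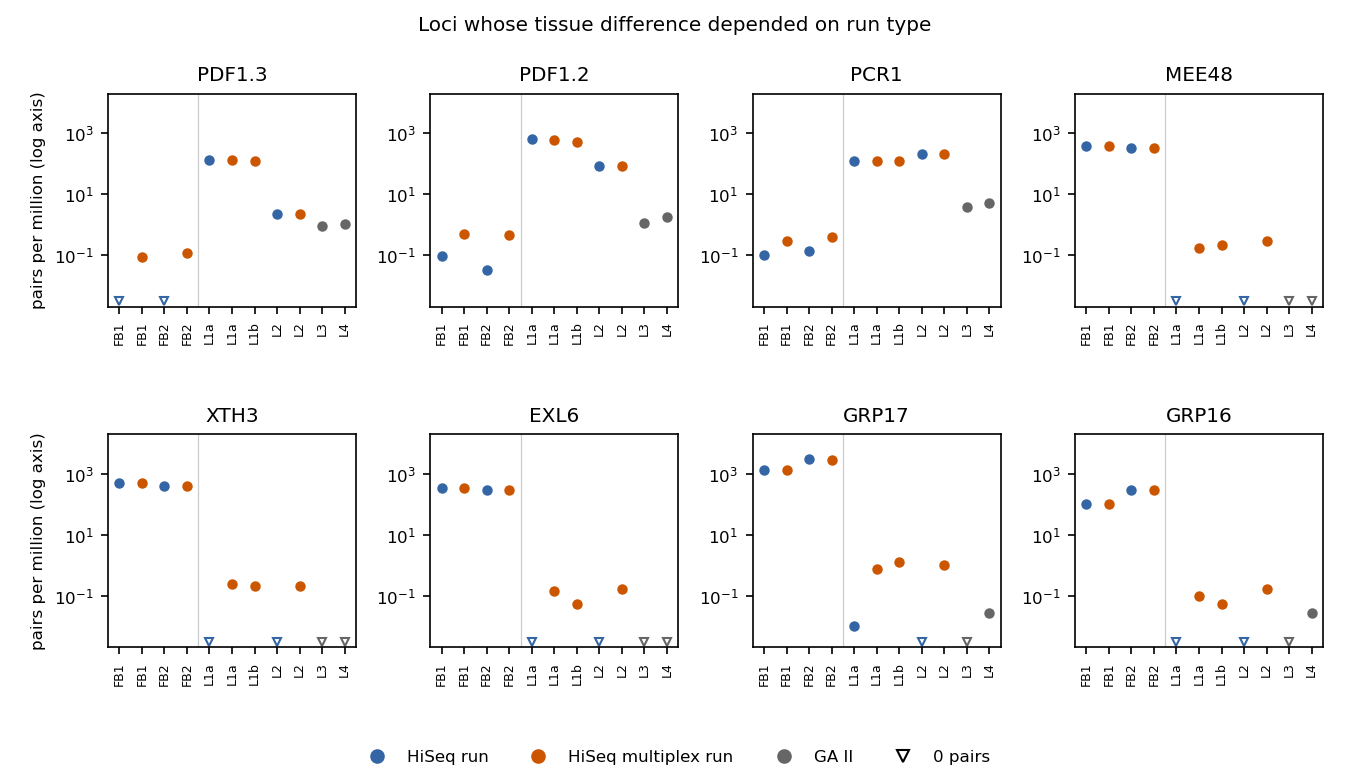
CPM without TMM scaling (y axis, log scale) of the 8 named loci in each of the 11 libraries (x axis), with HiSeq runs in blue, multiplex runs in orange, GA II in grey and 0 pairs as open triangles at the bottom. In the tissue where each locus is scarce, multiplex runs hold pairs, such as 30 and 39 for GRP17 in leaf 1a and leaf 2, where HiSeq runs hold 2 and 0.

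Leaf 3 and 4, sequenced on the GA II, were compared with leaf 1 and 2 from the HiSeq2000. Of the 24043 loci, 2916 were higher and 3652 lower in leaf 3 and 4 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), 2687 and 3202 of them by more than 2-fold. The 5 abundant loci with the largest rise included BT2, a BTB and TAZ domain protein, which rose by 11.35 ± 0.65 on the log2 scale (SE), AT5G28450, a chlorophyll-binding family gene, which rose by 7.82 ± 0.57, and AT1G69140, with 10888 pairs in leaf 3 and 4 against 2 in leaf 1 and 2. AT4G33467 and the copper amine oxidase gene AT1G31690 were the other 2. The 5 with the largest fall were FLP1, a flowering-promoting factor, with 11032 pairs in leaf 1 and 2 against 0 in leaf 3 and 4, at least 472-fold lower; PR1, a marker of salicylate defence, with 24343 against 1; the MADS-box gene AGL42, with 20869 against 1; the defensin PDF1.2c, with 54005 against 2; and AT4G19430, with 31508 against 2. Without leaf 4, the adjusted p of PDF1.2c and of AT1G31690 was 0.0520 and that of AT4G19430 was 0.0542.

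The gene lists were applied to this comparison after the data had been seen, and the members named for it were chosen after their values were seen. Of 32 cell cycle and DNA replication genes, 26 were higher and 0 lower in leaf 3 and 4, or 31 and 0 adjusted over the list alone (adjusted p = 2.24e-15; adjusted p = 0.670 with an estimated correlation). MCM5, a replication helicase subunit, stood at 27.0 ± 2.81 CPM in leaf 3 and 4 and 2.21 ± 1.70 in leaf 1 and 2 (SD, n = 2 each). Of 24 ribosomal protein genes, 21 were higher and 1, RPS9C, lower, or 23 and 1 adjusted over the list alone (adjusted p = 9.97e-10; adjusted p = 0.549 with an estimated correlation). Of 14 chlorophyll synthesis genes, 8 were higher and 0 lower, also when adjusted over the list alone (adjusted p = 4.26e-05; adjusted p = 0.670 with an estimated correlation), among them PORB, a protochlorophyllide reductase, at 3264 ± 209 against 156 ± 33.2 CPM. Of 50 photosystem genes, 4 were higher and 1 lower, or 0 and 1 adjusted over the list alone (adjusted p = 4.69e-06; adjusted p = 0.936 with an estimated correlation). Of 24 meiosis genes, 4 were higher and 1 lower, or 4 and 0 adjusted over the list alone (adjusted p = 0.0468; adjusted p = 0.670 with an estimated correlation). Of 20 senescence and chlorophyll breakdown genes, 10 were lower and 1 higher, or 11 and 1 adjusted over the list alone (adjusted p = 0.00125; adjusted p = 0.444 with an estimated correlation). NAP, a NAC factor that promotes leaf senescence, fell by 4.55 ± 0.64 on the log2 scale (SE), and SAG13, a senescence marker, stood at 0.137 ± 0.0436 CPM in leaf 3 and 4 and 63.3 ± 18.5 in leaf 1 and 2. DIN10, a gene induced by sugar starvation, was the higher member, at 115 ± 23.5 against 3.47 ± 0.570. Without leaf 3, the number called higher was 4 for the cell cycle list, 1 for ribosomal proteins and 0 for chlorophyll synthesis, photosystems and meiosis. Without leaf 4 it was 1 for the cell cycle list and 0 for the other 4 lists, and 3 senescence genes were called lower. Without leaf 1, 27 photosystem genes were called higher, and 21 by DESeq2.

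Of 24 salicylate and pattern-triggered defence genes, 9 were lower and 1 higher in leaf 3 and 4, or 11 and 1 adjusted over the list alone (adjusted p = 0.000537; adjusted p = 0.444 with an estimated correlation). PR2 fell by 6.43 ± 0.67 on the log2 scale (SE), and PBS3, a salicylate synthesis gene, stood at 4.28 ± 0.403 CPM against 21.6 ± 9.01 in leaf 1 and 2 (SD, n = 2 each). WRKY18, a transcription factor, was the higher gene. Of 15 flowering time genes, 8 were lower and 1 higher, or 9 and 2 adjusted over the list alone (adjusted p = 0.00360; adjusted p = 0.444 with an estimated correlation). FT, the mobile florigen made in leaves, had 12497 pairs in leaf 1 and 2 and 1 in leaf 3 and 4, a ratio of 1605 (interval 288 to 63412), and its relative TSF had 2010 and 0, at least 86.1-fold lower. SOC1, which is activated downstream of FT, stood at 36.3 ± 0.0901 CPM against 116 ± 1.05, and FLC, the higher gene, at 4.65 ± 0.271 against 0.103 ± 0.140. The clock list had 6 genes higher and 8 lower, or 7 and 9 adjusted over the list alone (adjusted p = 0.966, and fry's adjusted p = 0.0104 for change in either direction). That value of fry was 0.00636 for reference genes for qPCR, so it does not set clock genes apart. The clock list's median was 0.11 and its test pointed down. Its morning gene CCA1 stood at 18.3 ± 5.06 CPM in leaf 3 and 4 against 285 ± 167 in leaf 1 and 2, and its evening gene TOC1 at 89.4 ± 23.7 against 21.0 ± 14.8. Without leaf 3, 3 salicylate, 3 flowering time and 3 clock genes were called lower and 1 clock gene higher. Without leaf 4, 3 salicylate, 2 flowering time and 0 clock genes were called lower and 1 clock gene higher.

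**Figure D4:**
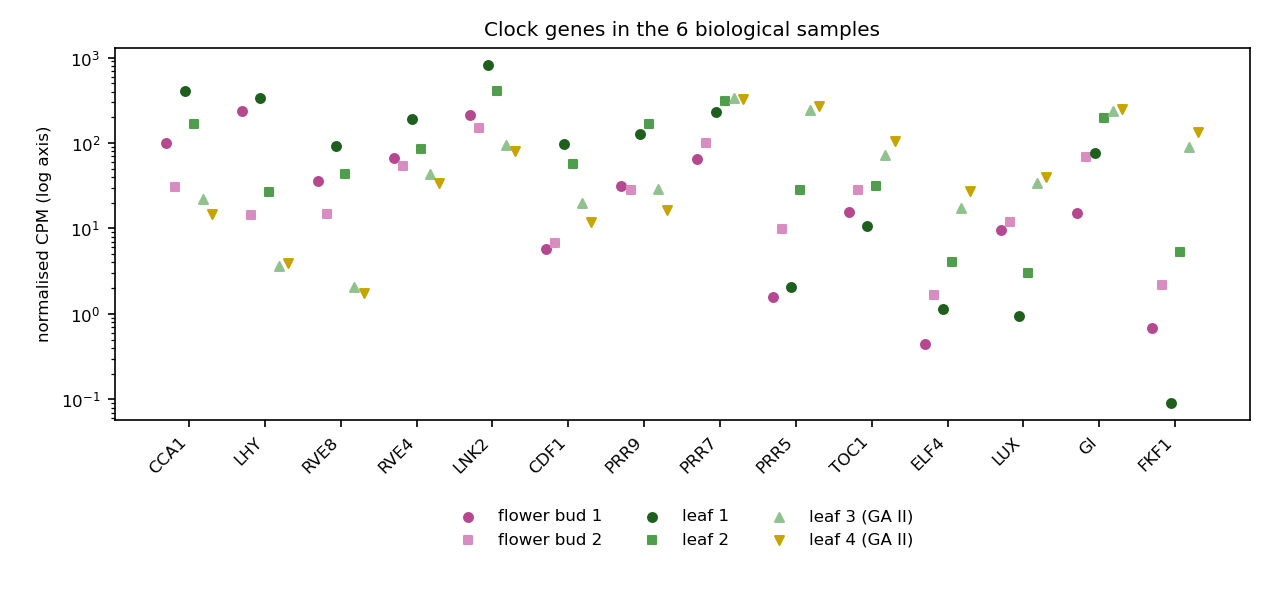
Normalised CPM (y axis, log scale) of 14 clock genes (x axis) in each of the 6 biological samples. Leaf 3 and 4 lie below leaf 1 and 2 for the morning gene CCA1, at 18.3 ± 5.06 against 285 ± 167 CPM (SD, n = 2 each), and above them for the evening gene TOC1, at 89.4 ± 23.7 against 21.0 ± 14.8.

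The median and the mean differed in sign in this comparison for shoot meristem, Calvin cycle, jasmonate, secondary wall and heat genes, and these lists had adjusted p-values of 0.575 or more. The number of calls between leaf samples fell when leaf 3 or leaf 4 was left out: without leaf 3, 371 loci were higher and 426 lower, and without leaf 4, 213 and 261. With library size only, 2394 were higher and 4647 lower, with the median of all loci shifted by -0.20, and upper quartile factors shifted it by 0.16. No leaf sample was run on both sequencers, so the sequencer and the plants cannot be told apart.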

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

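The tests of scaling factors, misassigned pairs, flower bud material, depth, GC content and length, the sequencer, the time of day and abundant leaf loci were chosen after the results they bear on had been seen, and that of multiplex pairs in the leaf comparison after the data had been seen but before its own value was known.

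The tissue difference of 157 loci depended on run type, by a test of the interaction. On the log2 scale the interaction was 6.23 for PDF1.3, 2.80 for PDF1.2 and 1.43 for PCR1, all lower in flower buds, and -8.07 for MEE48, -8.02 for XTH3, -7.46 for EXL6, -7.22 for GRP17 and -7.21 for GRP16, all higher in flower buds. A positive value means a higher log2 fold change of flower buds over leaves in the multiplex runs. For loci lower in flower buds this is a smaller tissue difference in those runs. A negative value is a smaller one for loci higher in flower buds.

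Of those 157 loci, 114 had an interaction of 2-fold or less, and with library size only 4 of them were still called: their median log2 interaction went from -0.07 to -0.03 while the median SE went from 0.0182 to 0.0126, so the calls ended with the shift of the scaling factors and not with a wider error. Of the other 43, 36 were still called with library size only, which argues against scaling as their cause. Flower bud material in a leaf library would enter both of its runs, so the HiSeq run would hold the pairs predicted from the multiplex run, a ratio of 1. This was measured over 243 loci picked on flower bud HiSeq runs and GA II leaves alone, of which 25 had a called interaction. The ratio was 0.763 in leaf 1a (95% counting interval 0.715 to 0.815) and 0.540 in leaf 2 (0.504 to 0.580). Both intervals lie below 1, which argues against material that enters both runs alike as the cause of the multiplex excess at these loci. In leaf 1a the interval was not under the bound of 0.8 set for excluding it. Such material may still make up part of the pairs that both runs hold. Pairs assigned to the wrong multiplex library are a candidate explanation. A first test of it, over 44 uncalled anther and pollen genes, gave 130 excess pairs with a counting SE of 86.9, which decided nothing. The regression over the 23506 uncalled loci that then replaced it gave an excess of 0.0156% ± 0.00124 of the flower bud pairs in leaf 1a and 0.0283% ± 0.00108 in leaf 2 (SE). At the 39 loci with a called negative interaction over 2-fold the excess was 0.0230% and 0.0349%. Those loci were called on the same libraries, which favours loci with such an excess. The labels do not say which libraries shared a lane, carry-over before sequencing stays open, and no biological explanation was tested.

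Leaf 3 and 4 differed from leaf 1 and 2 at 6568 loci, while 371 were called higher and 426 lower without leaf 3, and 213 and 261 without leaf 4. Of the 6568 loci, 91.7% stayed called with all libraries thinned to the smallest total, 84.3% with the trend on GC content and length removed, and 98.04% with the HiSeq runs alone for leaf 1 and 2, which argues against depth, that trend or multiplex pairs as the whole cause. The number of leaf samples run on both sequencers was 0, so the sequencer and the plants cannot be told apart. Another time of day at harvest may account for the clock genes: of 9 evening members 5 were called higher in leaf 3 and 4 and 0 lower, and of 9 morning members 8 were called lower and 0 higher, with medians of 2.17 and -2.69, a difference of 4.86 on the log2 scale. The labels give no harvest time, and a difference in age or growth between the plants was not tested.

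The number of loci called higher and lower between tissues moved with the scaling. With library size only, the median of all loci shifted by 0.58 on the log2 scale, and with the 50 most abundant leaf loci left out it shifted by 0.38. The shift kept 64.7% of its size, between the bounds set for and against a few abundant loci as its cause, so their part could not be decided.

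Among 124 named genes, 19 had 1 leaf sample far from the other 3. For 8 of these the other 3 samples held 0 pairs, so that the few pairs of 1 sample set the result: CRC, STK and GL1 at 0.00430 CPM, WUS at 0.00859 and AT4G14815 at 0.0129 in leaf 1, YUC1 at 0.00911 and HTR10 at 0.00456 in leaf 2, and LFY at 0.0335 in leaf 4. Of the 116 genes left, 11 were apart. Chance gives about 1 gene in 20 only for samples that vary alike, and leaf 3 and 4 differed from leaf 1 and 2 at 6568 loci. The 11 genes can therefore not be read against that share. In leaf 1 the highest values were 563.5 CPM for CYP79F1 and 702.9 for PDF1.2. In leaf 2 they were 5.36 CPM for NRT2.1, 646.8 for AT1G15125, 3.69 for 5MAT, 15.1 for LDOX, 43.5 for DFR, 13.8 for UGT79B1 and 0.159 for SYN1. AT3G16670 was lowest in leaf 2, at 1.14 CPM, and TCH3 was highest in leaf 3, at 227 CPM.

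Between HiSeq and multiplex runs, the 8 libraries allow 8 splits that part the runs of every sample, too few for a share under 0.05. The real split called 0 loci and the highest of the others called 0.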

How the results depend on the processing

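The fits on single reads, on pairs within the insert limit, without multiplex runs but with the GA II kept, with 1b in place of 1a for the dependence on run type, and with HiSeq runs alone for leaf 1 and 2 were chosen after the data had been seen.

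Between tissues, 7322 loci higher and 5017 lower became 4796 and 2397 with no sequencer term, which adds leaf 3 and 4 to the comparison. With library size only 2991 were lower, and 2642 with glmTreat, which asks for more than 2-fold. Leaving out 1 sample gave 4596 to 7607 higher, the fewest without flower bud 1, and 3754 to 4971 lower. DESeq2 gave 7336 and 5531, and limma-voom 8612 and 6462.

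Between run types, the 0 loci called became 15 with RLE factors, 9 with upper quartile factors, 4 with library size only, 3 in thinned libraries, 6 without organelle loci, 6 within flower bud pairs, 23 within leaf pairs and 1 with 1b in place of 1a. The cause was not tested. The dependence on run type fell from 157 loci to 37 with RLE factors, 36 with upper quartile factors, 40 with library size only, 83 at a mean of 1 CPM or more, 68 without organelle loci, 76 with 1b and 29 with DESeq2, and was 273 with no filter. It was 40 in thinned libraries, 21 of them positive, and 81 to 711 without 1 sample, mostly positive without leaf 1 or leaf 2. Scaling apart, the cause was not tested.

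Between leaf samples, leaving out 1 sample gave 213 to 3644 loci higher and 261 to 3669 lower, the fewest without leaf 4 and then without leaf 3, where 371 and 426 were called. With leaf 3 or leaf 4 left out, the spread came from the HiSeq2000 samples alone. These varied more, with coefficients of variation of 31.2% to 39.8% against 10.7% between leaf 3 and 4. Whether this was the cause was not tested. Other settings gave 2394 to 4288 higher and 2884 to 4647 lower. A lone sample left in a group was assumed to vary like the others.

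Of the 15 lists called with a preset correlation, 0 were called with an estimated one. Flavonoid genes called higher ranged from 5, without flower bud 1, to 14, without leaf 1. With no sequencer term 1 senescence gene was called lower, DIN10 had a log2 fold change of -0.27 and LUX -0.85, where leaf 3 and 4 stood above leaf 1 and 2. With library size only, 2 guard cell and trichome genes and 2 reference genes were called lower while the median of all loci shifted. In both lists more were then called higher than lower, the reverse of the main fit. Leaf 1a and 1b had a chi-square per degree of freedom of 4.95 at an expected count of 50 or more.

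The replicate block gave 6899 loci higher and 4789 lower between tissues in the HiSeq2000 samples, and without a replicate block the run comparison called 0, with 4 at an unadjusted p under 0.05. The labels state no pairing of flower buds with leaves. Across loci, which are not independent, the difference between sample 1 and 2 in flower buds and that in leaves had r = 0.292 and rho = 0.326, over 2 pairs.

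Over all settings, values of the named genes of the tissue comparison kept their direction and call in 3112 cases, lost the call in 134 (53 genes) and changed sign in 2. Between leaf samples 157 were kept and 3 lost, and for the dependence on run type 88 and 16. Depth limits loci near 3 pairs, 0.0156 CPM in the deepest and 0.0872 CPM in the shallowest library.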

Other observations

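The gene families and the limits for restricted loci were chosen after the data had been seen, and so were the loci named from them.

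Families named by the reference annotation were compared with all 21494 tested loci with a product name other than uncharacterised, hypothetical or the like, of which 30.8% were higher and 20.8% lower in flower buds. Over 137 families of 20 or more loci, 24 held more higher loci and 17 more lower loci than that background (Fisher's exact test with Benjamini-Hochberg adjustment). The lowest adjusted p for higher loci was that of genes with F-box and associated interaction domains, 70 of 98 (adjusted p = 3.50e-14), followed by low-molecular-weight cysteine-rich genes, 26 of 27 (adjusted p = 6.12e-11), invertase or pectin methylesterase inhibitors, 42 of 55 (adjusted p = 2.25e-10, and 18 of 33 with adjusted p = 0.0247 under another spelling of the name), and pectin lyase-like genes, 53 of 80 (adjusted p = 3.20e-09). Also higher were 19 of 21 self-incompatibility S1 genes (adjusted p = 5.88e-07), 24 of 32 histones (adjusted p = 8.89e-06) and 18 of 22 defensin-like genes (adjusted p = 2.53e-05). The lowest adjusted p for lower loci was that of disease resistance genes of the TIR-NBS-LRR class, 40 of 58 (adjusted p = 5.38e-13), followed by receptor like proteins, 34 of 50 (adjusted p = 6.12e-11), cysteine-rich receptor kinases, 24 of 33 (adjusted p = 8.87e-09), and disease resistance genes of the CC-NBS-LRR class, 19 of 24 (adjusted p = 5.44e-08). Of 48 WRKY factors, 25 were lower and 8 higher (adjusted p = 3.53e-05 for lower). Members of a family can share reads, so they are not independent.

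Outside the multiplex runs, 200 loci had at least 10 CPM in both flower bud libraries and under 0.1 CPM in every leaf library, with TMM scaling. Among them were the tapetal glucosidase gene ATA27, at 943 and 983 CPM, the pollen coat gene GRP19, at 986 and 873, the petal and stamen identity gene AP3, at 168.7 and 129.7, ACOS5, which acts in pollen wall synthesis, at 211 and 115, and AGO9, an Argonaute gene, at 59.2 and 84.0. The reverse held for 1 locus, the TRAF-like AT4G01390, at 50.3 and 93.2 CPM in leaf 1 and 2 and 14.5 and 14.2 in leaf 3 and 4. With leaf 1 and 2 alone it held for 8 loci, among them ORA59, a factor of jasmonate and ethylene response, at 14.1 and 14.8 CPM, and the receptor kinase CRK23, at 18.7 and 39.7.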
